A study of Homo sapiens with 8 samples.

How the data were processed

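RNA from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was measured on 8 arrays. Per the labels, the cells grew in DMEM with 5% serum, 3 samples were infected with Shigella flexneri M90T, 3 were treated with rapamycin and 2 were untreated controls. Infection was a 20 min incubation at room temperature followed by 4 h in gentamicin medium, and rapamycin was given at 50 ug/mL for 4 h with similar media and washes. Per the labels, each sample came from an experiment of its own and 1 further control was lost to RNA degradation. RNA was extracted in Trizol and labelled with biotin, per the labels' protocols. The number of arrays limits the precision.

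The deposited values are log2 signals of 410347 probesets, which are groups of probes that each read 1 stretch of a transcript. Per the submitters' processing notes, the authors used Affymetrix Power Tools and RMA with genome build hg18; their versions and the background settings are not given in the sources used here. The values ran from 1.17 to 14.67 and the array medians from 7.68 to 7.84, so no further normalization was applied. A separate measure of signal over background was not used here. The series' design text names AltAnalyze with default settings for the pairwise comparisons with uninfected cells.

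Probesets were named through the platform's annotation. Exactly 1 gene symbol was given for 218298 probesets, several for 7752 and none for 184297, and probesets of the last 2 kinds named no gene. Of 17891 symbols, 15159 were current in a RefSeq gene table of assembly GRCh38, 2626 were updated through it and 106 were left as given. The table served for names alone, and no coordinates are given because it is of another build than the values. A gene's value was the mean log2 value of all its probesets, which gave 17843 genes with a median of 9 probesets and at most 133, and 1491 genes rested on 1 probeset. Probes for near-identical genes, such as the metallothioneins or the CXCL chemokines, can share signal.

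All 8 arrays entered 1 linear model with a mean per group, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with data.table (version 1.17.8). The fit had 5 residual degrees of freedom and 5.28 prior ones. Every adjusted p for a gene comes from this limma test with Benjamini-Hochberg adjustment over all genes within a comparison, two-sided, and a gene counted as changed with an adjusted p under 0.05. A 2-fold count adds an absolute log2 change of at least 1. Shigella minus control and rapamycin minus control share their 2 controls; Shigella minus rapamycin uses no control in its difference. Errors beside log2 changes are standard errors from the model, and errors of group means are SDs.

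Gene lists for 20 pathways and marker lists for 5 cell types were fixed before the data were examined, as were the model, the threshold, the alternatives named as such and the rule for naming genes. Lists were tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 20 lists within a comparison, and again with the correlation estimated per list. Camera compares a list with all other genes. The named genes were the 10 with the largest change in each direction among those past the threshold whose arrays all lay on one side of the other group's; with fewer than 5 in a direction, the 5 with the smallest unadjusted p; up to 4 members with the smallest p from each list; and 20 genes named whatever they did, of which 2 are not analysed here. For probesets, the rule took the 5 with the smallest p and an absolute log2 difference of at least 1. Other genes that appear in the text were chosen after their values were seen.

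Single probesets were set against the rest of their gene with diffSplice of limma in genes with at least 4 probesets, which is 210792 probesets in 13898 genes. Beside it, each probeset's difference from the mean of its gene's other probesets was tested with its own spread, a test chosen after seeing the data. The overlap of both responses was set beside 100 simulated data sets in which no group differed from the same 2 controls.

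The gene test was tested on simulated data drawn with the spread of the real genes. For Shigella minus control it recovered 87% of 100 genes changed by a log2 value of 1 and 100% of those changed by 2, and it called 12 unchanged genes. For Shigella minus rapamycin it recovered 94% and 100%, and it called 14 unchanged genes. Benjamini-Hochberg adjustment is easier to pass when many genes change. These shares hold for 100 changed genes of each size and may overstate recovery in the real data, where fewer genes passed. No gene was changed for rapamycin minus control, so recovery there was not tested. For Shigella minus control, camera called 1 of 1 raised list and 0 of 19 unchanged lists. The simulated genes were independent, so this does not show how often camera calls unchanged lists of correlated genes. In the real data the correlation estimated between members was 0.157 for the amino acid response and 0.683 for cytosolic ribosomal proteins. In simulated data with no change in any probeset, diffSplice called 197 probesets for Shigella minus control and 173 for rapamycin minus control, and the test with each probeset's own spread called 0 in both.

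The alternatives were the median of a gene's probesets, the mean of its brighter probesets (from the middle rank of mean signal upward), quantile normalization, a common array median, a filter at the 33rd percentile of signal, only the 2 groups compared, the replicate number as a block, an intensity trend in the prior, an unadjusted p with a 2-fold change, array weights, an estimated correlation, at least 10 probesets per gene, and leaving out each array in turn. Control 2, Shigella 3 and rapamycin 3 deviated together from their groups and are called the smaller array set; the other 5 arrays are the larger set. No label explains this split, although Shigella 3 and rapamycin 3 share a number and which control was lost was not established. The split was found in the values after they were examined. Fits with the array set as a block, or on the larger set alone, were therefore added after seeing the data. Because such a block removes spread that was picked out from the same values, its p-values are too small by an amount that was not measured. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.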

Results

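Gene expression was measured with exon arrays in HEK293T cells after infection with the invasive bacterium Shigella flexneri (3 arrays), after treatment with rapamycin, an inhibitor of the mTOR kinase complex 1 (3 arrays), and in untreated cells (2 arrays). The design compares untreated cells with infected cells and with rapamycin-treated cells after 4 h. Whether the control cells were washed, or given solvent, like the treated cells is not given in the sources used here, so differences from the controls may include an effect of those steps. Each array gave a value for 17843 genes, and correlations across genes between arrays of one group lay between 0.941 and 0.982. The first principal component held 38.8% of the variance and separated control 2, Shigella 3 and rapamycin 3 from the other 5 arrays, while the second held 22.3% and separated the rapamycin arrays from the Shigella arrays.

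**Figure D1:**
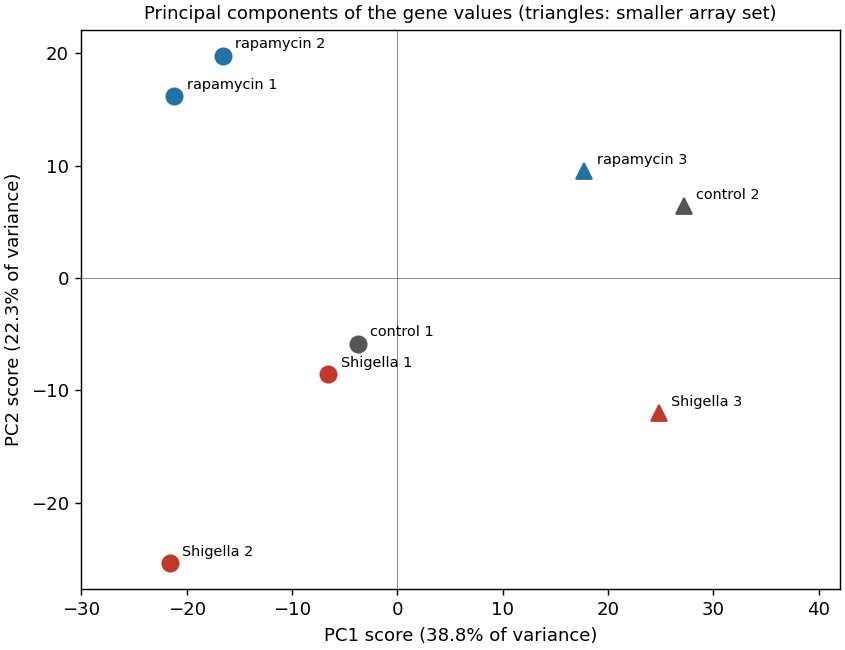
Scores of the 8 arrays on the first principal component (38.8% of the variance, x axis) and the second (22.3%, y axis) of the gene values; each point is 1 array, coloured by group. The 3 arrays drawn as triangles lie at positive scores of the first component, and on the second component all 3 rapamycin arrays lie above 0 and all 3 Shigella arrays below 0.

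Infected cells carried more RNA for the chemokines CXCL10 and CXCL8 and for TNFAIP3 and NFKBIA, which restrain NF-kappaB, a transcription factor of inflammation. CXCL10 and CXCL8, which attract T cells and neutrophils, rose 7.77-fold (log2 2.96 ± 0.24 SE, adjusted p = 0.000915) and 7.13-fold (log2 2.83 ± 0.26, adjusted p = 0.00124) in 3 Shigella arrays against 2 controls. TNFAIP3, a ubiquitin-editing enzyme that restrains NF-kappaB signalling, rose 5.86-fold (log2 2.55 ± 0.16), and NFKBIA, which holds NF-kappaB in the cytoplasm, rose 4.74-fold (log2 2.24 ± 0.14), each with adjusted p = 0.000102. PTX3, a secreted pattern recognition protein, rose 8.62-fold (log2 3.11 ± 0.28, adjusted p = 0.00124) and TNFRSF9, a TNF receptor family member, 8.00-fold (log2 3.00 ± 0.19, adjusted p = 0.000102). SOX2, a transcription factor of stem and progenitor cells, was the 1 gene that fell, to 0.549 of its control level (log2 -0.87 ± 0.13, adjusted p = 0.0436).

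In all, 23 genes changed with infection, 22 of them higher, and 18 changed at least 2-fold, all higher. Every Shigella array lay beyond both controls for each of the 23. The test that chose them used these same arrays, so this separation gives no separate support. The control means of CXCL10 (3.89), PTX3 (5.06), CXCL8 (5.70), TNFRSF9 (5.86) and PLA2G4C (5.86) lay under the lower quartile of probeset values on every array (6.72 to 6.90), as did their rapamycin means. No measure of background was used here, so folds against these levels are those of the deposited signals and may understate the change in RNA. Further genes with large increases were CALCB, a calcitonin gene-related peptide (4.17-fold, adjusted p = 0.0297), SDC4, a heparan sulfate proteoglycan (3.31-fold, adjusted p = 0.00124), PLA2G4C, a cytosolic phospholipase A2 (2.92-fold, adjusted p = 0.0436), and the NF-kappaB subunit RELB (2.88-fold, adjusted p = 0.016). The genes next in p below SOX2 did not pass: RAB38 (log2 -1.03, 1 probeset), HOXA11 (-0.83), TFAP2A (-0.76) and ISL1 (-0.74) had adjusted p from 0.131 to 0.261.

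Of the 30 measured genes of the NF-kappaB and inflammatory list, 10 rose, 17 when adjusted over the list alone, and none fell. The list's median log2 change was 0.79, with camera's adjusted p = 3.39e-46 and adjusted p = 0.00445 with an estimated correlation. Its median was 0.72 within the larger array set and 0.87 within the smaller one. Of 35 immediate early and AP-1 genes, 2 rose, 12 when adjusted over the list alone. These were DUSP8, a MAP kinase phosphatase (2.30-fold, adjusted p = 0.016), and GADD45B, a stress-response protein (2.45-fold, adjusted p = 0.0163). The phosphatase DUSP1 (log2 1.18, adjusted p = 0.0812), PPP1R15A (0.90, adjusted p = 0.131) and JUN (1.06 ± 0.26, adjusted p = 0.445) did not pass. The median of this list was 0.22 (camera adjusted p = 2.47e-20), and the call was lost with an estimated correlation (adjusted p = 0.0922). FOS (log2 0.36) and EGR1 (0.22) did not pass (adjusted p = 0.998 each).

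Among 37 amino acid response genes, targets of the transcription factor ATF4, 1 rose with infection. That gene was ATF3, a stress-induced transcription factor (2.82-fold, adjusted p = 0.0436). CHAC1 (log2 0.67, adjusted p = 0.567), DDIT3 (0.47), SLC7A11 (0.42), SLC7A1 (0.30), ASNS (0.24), SESN2 (0.19) and TRIB3 (-0.03) did not pass (adjusted p = 0.998 for the last 6). The list's median was 0.09 (camera adjusted p = 7.01e-05), a call lost with an estimated correlation (adjusted p = 0.41). The same held for 4 lists in which no gene passed limma's test over all genes. Their medians were 0.10 for the interferon response (camera adjusted p = 0.0389, adjusted p = 0.271 with an estimated correlation), 0.09 for cytosolic ribosomal proteins (0.00575 and 0.675), -0.16 for FOXO targets (0.00575 and 0.303) and -0.11 for mTOR pathway components (0.035 and 0.674). At an unadjusted p under 0.05, 6 of 22 FOXO targets and 4 of 27 mTOR pathway components were lower, 3 of 26 interferon response genes were higher and 2 lower, and 0 of 48 ribosomal protein genes were on either side. The interferon-response members IRF1 and IFIT3 lay at log2 0.40 and 0.43, and HERC5 and IFI44L at -0.46 and -0.41 (adjusted p = 0.998 each). Within the larger and the smaller array set the medians were 0.07 and 0.13 for the amino acid response, 0.26 and 0.40 for immediate early genes, 0.04 and 0.12 for the interferon response, -0.19 and -0.12 for FOXO targets, and -0.15 and -0.0060 for mTOR pathway components. With the preset correlation, the interferon call ended without control 1, Shigella 2 or Shigella 3, with quantile normalization, above the 33rd percentile of signal, with only the 2 groups compared and in the larger array set (adjusted p from 0.0571 to 0.732). The ribosomal protein call ended without control 2, Shigella 1 or Shigella 2, with quantile normalization and with the array set as a block (0.0717 to 0.928). The call of mTOR pathway components ended without control 1, control 2 or Shigella 2, with the median or the brighter probesets, with quantile normalization, above the 33rd percentile, with only the 2 groups compared and in the larger array set (0.0501 to 0.461).

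The other 13 lists did not pass camera's test for infection (adjusted p from 0.0599 to 0.671). Their medians were -0.11 for heat shock, -0.09 for the unfolded protein response, -0.11 for sterol and lipid synthesis, -0.07 for glycolysis and HIF1 targets, 0.0067 for ribosome biogenesis, 0.01 for lysosome and autophagy, 0.02 for G1/S and DNA replication and -0.09 for G2/M. They were 0.02 for p53 targets and apoptosis, -0.10 for NRF2 targets, 0.10 for metallothioneins, -0.04 for innate sensors of bacteria and -0.06 for actin cytoskeleton genes. Median and mean differed in sign for ribosome biogenesis (mean -0.02), G1/S (-0.0037), innate sensors (0.02) and actin (0.03), and camera's direction was up for all 4. GABARAPL1, of the autophagy list (log2 0.61, adjusted p = 0.37), BTG2, of the p53 list (0.65, adjusted p = 0.378), ANKRD1, of the actin list (0.79, adjusted p = 0.445), and RIPK2, the kinase downstream of the NOD sensors (0.35, adjusted p = 0.998), did not pass.

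The number of genes changed with infection depended on single arrays, also on rapamycin arrays, which enter only the estimate of spread. It was 10 without control 1, 7 without control 2, 7 without Shigella 1, 11 without Shigella 3, 15 without rapamycin 1 and 12 without rapamycin 2, and none of the 23 changed sign in any of these fits. SOX2 lost its call without any one of the 8 arrays (adjusted p from 0.0576 without rapamycin 3 to 0.604 without control 2), and ATF3 lost it without either control, any Shigella array or rapamycin 2 (adjusted p up to 0.561 without control 2). CALCB, PLA2G4C, RELB, DUSP8 and GADD45B lost theirs without control 2 (adjusted p from 0.239 to 0.501) and without Shigella 1 (0.156 to 0.286), among other arrays. CXCL10, CXCL8, TNFAIP3, NFKBIA, PTX3, TNFRSF9 and SDC4 passed without any one array (adjusted p at most 0.0202), and PTX3 did not pass with the median over probesets (adjusted p = 0.0775). With only the brighter probesets of each gene, CXCL10 lay at log2 2.00 (adjusted p = 0.0357), CXCL8 at 2.24 (adjusted p = 0.00745) and PLA2G4C at 0.72 (adjusted p = 0.597), and CALCB, RELB, SOX2, ATF3 and DUSP8 did not pass (adjusted p from 0.0673 to 0.134). With the median over probesets PLA2G4C, CALCB, SOX2, ATF3, DUSP8 and GADD45B did not pass (adjusted p from 0.0775 to 0.624). With the array set as a block the count was 47, including all 23.

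**Figure D2:**
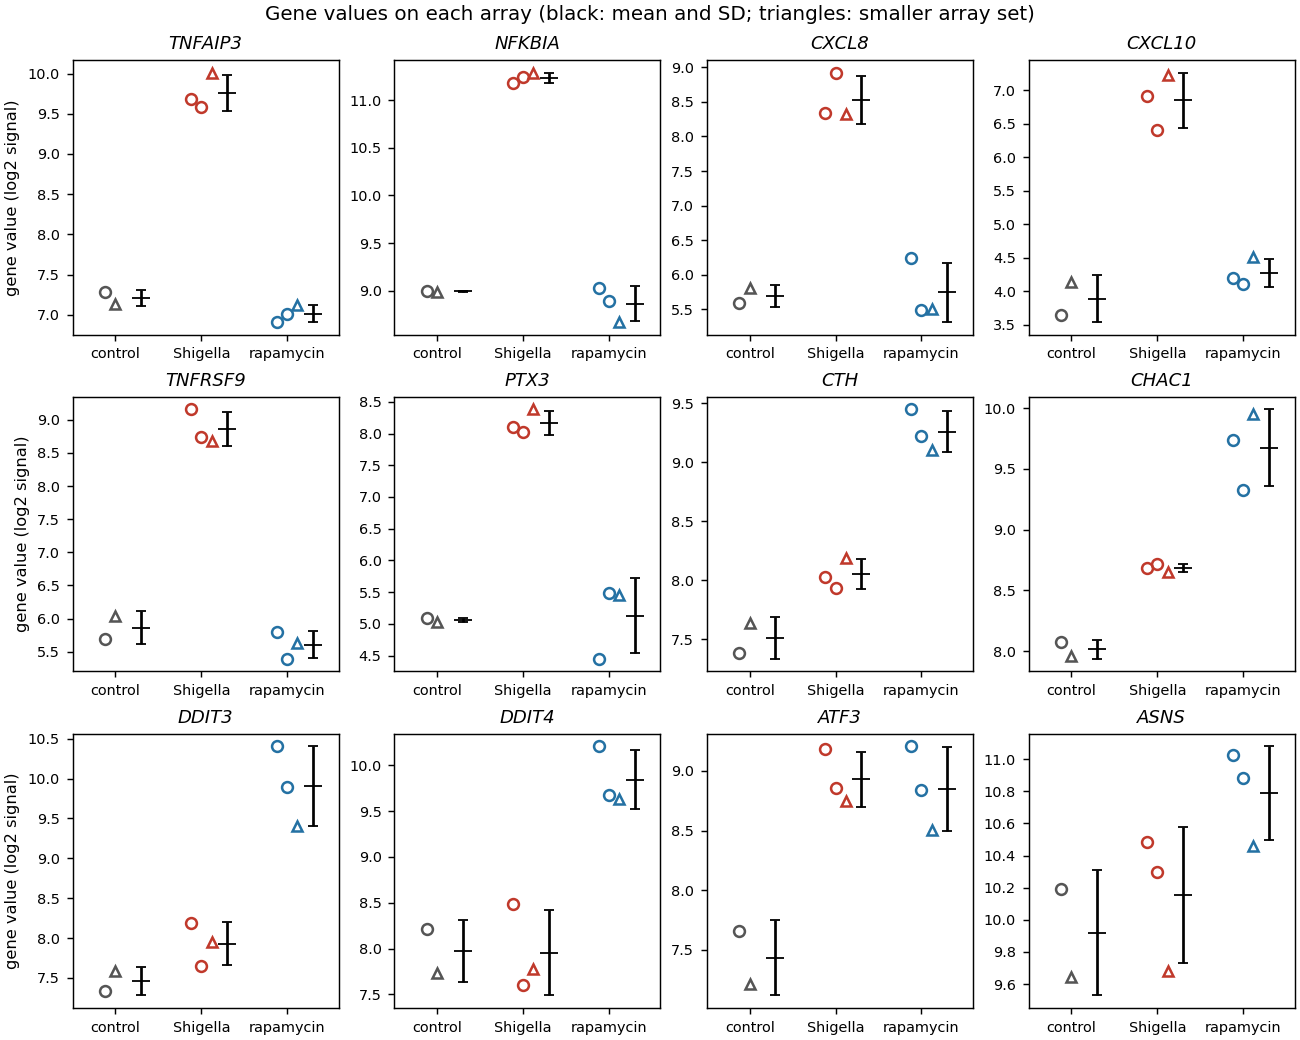
Gene values (log2 signal, y axis) of 12 genes on each of the 8 arrays by group (x axis, 2 control, 3 Shigella and 3 rapamycin arrays); circles are arrays of the larger array set and triangles those of the smaller, and black bars give the group mean ± SD. For TNFAIP3, NFKBIA, CXCL8, CXCL10, TNFRSF9 and PTX3 the 3 Shigella arrays lie above all other arrays, and for CTH, CHAC1, DDIT3 and DDIT4 the 3 rapamycin arrays do.

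With rapamycin, 3 genes changed, and all were higher. DDIT3, the stress-induced transcription factor CHOP, rose 5.45-fold (log2 2.45 ± 0.26 SE, adjusted p = 0.0154, 2 probesets) in 3 rapamycin arrays against 2 controls. CTH, an enzyme that makes cysteine from cystathionine, rose 3.35-fold (log2 1.74 ± 0.16, adjusted p = 0.00864), and CHAC1, a glutathione-degrading enzyme, 3.16-fold (log2 1.66 ± 0.18, adjusted p = 0.0154). All 3 rapamycin arrays lay above both controls for each, on the same arrays that chose these genes. At an unadjusted p under 0.05 by limma's test there were 995 of 17843 genes, and 742 for infection. Both counts are near the share of 0.05 that would pass with no change in any gene.

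DDIT3 and CHAC1 belong to the amino acid response list of ATF4 targets, a name that gives no cause, since amino acid supply was not tested. Of the list's 37 measured genes 2 rose, 23 when adjusted over the list alone. Its median log2 change was 0.46, with 35 members above 0, camera's adjusted p = 9.15e-38 and adjusted p = 0.0387 with an estimated correlation. Within the larger array set the median was 0.46 and within the smaller 0.41, and with the array set as a block the estimated-correlation call was lost (adjusted p = 0.237). With the preset correlation the list's adjusted p ran from 2.46e-39 to 5.46e-23 over the 19 settings in which lists were tested, which leave out array weights. Members that did not pass over all genes were DDIT4, an inhibitor of mTOR complex 1 (log2 1.86 ± 0.28, adjusted p = 0.0955), SLC7A11, the cystine transporter (1.15 ± 0.15, adjusted p = 0.067), SESN2, a leucine sensor (0.97 ± 0.15, adjusted p = 0.0997), ATF3 (1.42 ± 0.23, adjusted p = 0.118), ASNS, asparagine synthetase (0.87 ± 0.26, adjusted p = 0.609), and TRIB3 (0.42 ± 0.16, adjusted p = 0.797). ARRDC3, an alpha-arrestin, had a log2 change of 1.30 (adjusted p = 0.0568).

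Of 20 unfolded protein response genes, none passed limma's test over all genes, 3 were higher when adjusted over the list alone and 6 had an unadjusted p under 0.05. The list's median was 0.27 (camera adjusted p = 2.03e-11, adjusted p = 0.195 with an estimated correlation). HERPUD1, a component of endoplasmic reticulum-associated degradation, lay at log2 1.22 (adjusted p = 0.0852), the co-chaperone DNAJB9 at 1.05 (adjusted p = 0.243) and the transcription factor XBP1 at 0.85 (adjusted p = 0.168). Of 10 genes of the metallothionein and zinc response list, all had a log2 change above 0, none passed over all genes, 5 were higher when adjusted over the list alone and 7 had an unadjusted p under 0.05. The median was 0.45 (camera adjusted p = 2.03e-11, adjusted p = 0.195 with an estimated correlation), with MT1X at 1.14 (adjusted p = 0.337), MT1F at 0.98 (adjusted p = 0.442) and MT2A at 0.58 (adjusted p = 0.609).

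Ribosome biogenesis genes had a median of -0.19 (camera adjusted p = 4.27e-06, adjusted p = 0.612 with an estimated correlation), with none of 27 past limma's test and 6 lower at an unadjusted p under 0.05. RRS1, an assembly factor of the large ribosomal subunit, lay at -1.06 ± 0.29 (adjusted p = 0.519), and POLR1B, a subunit of RNA polymerase I, at -0.46 (adjusted p = 0.742). Cytosolic ribosomal proteins had a median of 0.19 (camera adjusted p = 1.2e-07, adjusted p = 0.649 with an estimated correlation), which was 0.20 within the larger array set and 0.02 within the smaller. In the same order the medians were 0.35 and 0.15 for the unfolded protein response, 0.34 and 0.57 for metallothioneins, -0.13 and -0.28 for ribosome biogenesis and 0.02 and 0.11 for FOXO targets. None of those 48 genes passed limma's test and 1 had an unadjusted p under 0.05. Immediate early genes (median 0.12, camera adjusted p = 0.00336, 0.16 within the larger array set and -0.0077 within the smaller) and FOXO targets (0.08, camera adjusted p = 0.0192) lost their calls with an estimated correlation (adjusted p = 0.649 and 0.493). None of their members passed limma's test, and 7 of 35 (4 higher, 3 lower) and 3 of 22 had an unadjusted p under 0.05, among the latter KLHL24 (log2 0.91, adjusted p = 0.255), a FOXO target that was higher when adjusted over the list alone. With the preset correlation, the immediate early call also ended without control 2 (adjusted p = 0.0797) or rapamycin 1 (0.0802), and the FOXO call without control 1, rapamycin 1 or rapamycin 3 and in the larger array set (0.0575 to 0.338).

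The other 13 lists did not pass for rapamycin (camera adjusted p from 0.0511 to 0.88). Their medians were -0.07 for NF-kappaB and inflammatory genes, -0.04 for the interferon response, -0.20 for heat shock, 0.03 for sterol and lipid synthesis, -0.09 for glycolysis and HIF1 targets, 0.07 for lysosome and autophagy, 0.0088 for mTOR pathway components and -0.07 for G1/S. They were -0.02 for G2/M, -0.10 for p53 targets, -0.04 for NRF2 targets, -0.06 for innate sensors and -0.12 for actin cytoskeleton genes. For the interferon, NRF2 and innate sensor lists the median and mean lay below 0 while camera's direction was up. MTOR itself lay at log2 -0.13 ± 0.19 (adjusted p = 0.984), MYC at 0.57 ± 0.29 (adjusted p = 0.949) and the autophagy gene WIPI1 at 0.86 ± 0.22 (adjusted p = 0.476). Among genes below the controls, none passed: GCG (-1.04), PDGFD (-1.02), POLR1G (-0.79), FASTKD5 (-0.83) and BICD2 (-0.68) had adjusted p from 0.121 to 0.309.

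The rapamycin count depended on the probesets used and on single arrays, also on Shigella arrays, which enter only the estimate of spread. It was 0 without control 1, 0 without control 2, 0 without Shigella 1, 1 without Shigella 2, 5 without Shigella 3 and 14 without rapamycin 3, and 0 with only the brighter probesets of each gene or with only the 5 arrays compared. CHAC1 lost its call without rapamycin 1 (adjusted p = 0.0833) and DDIT3 without rapamycin 2 (adjusted p = 0.0765), and over the fits without 1 array the adjusted p of both ran up to 0.242. With the array set as a block 18 genes changed, including these 3.

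**Figure D3:**
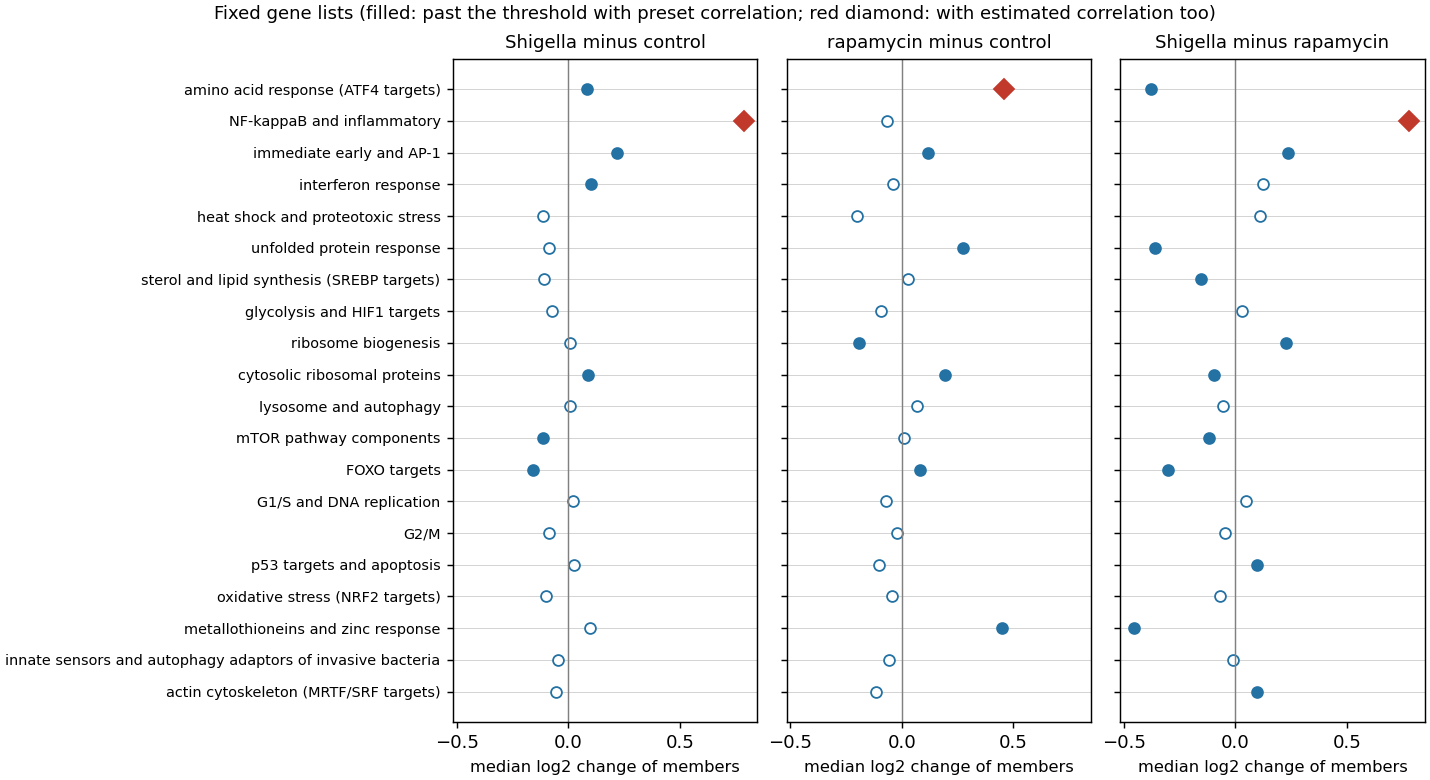
Median log2 change of the measured members of the 20 gene lists (x axis) in the 3 comparisons; filled symbols passed camera's test with the preset correlation, and red diamonds passed with an estimated correlation too. NF-kappaB and inflammatory genes had medians of 0.79 and 0.78 in the comparisons of infected cells, and amino acid response genes had a median of 0.46 with rapamycin and -0.38 in Shigella minus rapamycin.

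The direct comparison of both treatments, 3 arrays against 3, gave 99 changed genes, 50 higher with Shigella and 49 higher with rapamycin. TNFRSF9 was 9.56-fold higher with Shigella (log2 3.26 ± 0.17 SE, adjusted p = 1.83e-05), PTX3 8.22-fold (3.04 ± 0.25, adjusted p = 0.000591), TNFAIP3 6.70-fold (2.75 ± 0.14, adjusted p = 1.83e-05) and CCL20, a chemokine for immature dendritic cells, 3.08-fold (1.62 ± 0.23, adjusted p = 0.0151). CXCL8 (log2 2.78), CXCL10 (2.58), NFKBIA (2.37), SDC4 (1.93), IER3 (1.80) and RELB (1.62) were higher too, with adjusted p from 1.83e-05 to 0.00311. Lower with Shigella than with rapamycin were DDIT3 (log2 -1.97 ± 0.24, adjusted p = 0.007) and DDIT4 (-1.88 ± 0.25, adjusted p = 0.0105). The same held for HOXA5, a homeobox gene with 1 probeset (-1.53, adjusted p = 0.0119), ARRDC3 (-1.53, adjusted p = 0.00235) and ID3, an inhibitor of basic helix-loop-helix factors (-1.41, adjusted p = 0.0134). PJVK, HBP1, CTH, MT1F and PLPP5 followed with log2 differences from -1.25 to -1.18 and adjusted p from 0.00644 to 0.0431. ATF3 differed by 0.08 ± 0.20 (adjusted p = 0.942).

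Of these genes, 50 differed at least 2-fold, 31 higher and 19 lower with Shigella, and the arrays of both groups did not overlap for any of the 99. A separation of all 3 from all 3 arrays has a chance of 10% for a single unchanged gene. The 99 were chosen by a test on these same arrays, which favours separation, so it gives no separate support. The rapamycin mean of CCL20 (4.86, 2 probesets) and the lower group means of PJVK, HBP1, VLDLR, HSD17B7 and PLK2 (5.91 to 6.62) also lay under the lower quartile of probeset values on every array, so the limit on folds against dim levels holds for them too.

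NF-kappaB and inflammatory genes were higher with Shigella than with rapamycin in 16 of 30, or 21 when adjusted over the list alone, with a median of 0.78 (camera adjusted p = 1.06e-32, adjusted p = 0.0102 with an estimated correlation). With the array set as a block that last value was 0.0548, while with the preset correlation the adjusted p ran from 2.56e-37 to 6.47e-23 over the 19 settings in which lists were tested. Amino acid response genes were lower in 7 of 37, 18 when adjusted over the list alone, with a median of -0.38 (camera adjusted p = 4.54e-18, adjusted p = 0.0912 with an estimated correlation). These included CHAC1 (log2 -0.99, adjusted p = 0.0262), SESN2 (-0.78, adjusted p = 0.0328), the neutral amino acid transporter SLC1A4 (-1.02, adjusted p = 0.0119) and VLDLR (-0.92, adjusted p = 0.0232). Unfolded protein response genes were lower in 2 of 20, 9 when adjusted over the list alone, with a median of -0.36 (camera adjusted p = 5.23e-12, adjusted p = 0.129 with an estimated correlation), the 2 being HERPUD1 (log2 -1.17, adjusted p = 0.0117) and DNAJB9 (-1.11, adjusted p = 0.0262).

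FOXO targets were lower with Shigella in 2 of 22, 9 when adjusted over the list alone (median -0.30, camera adjusted p = 2.57e-06, adjusted p = 0.0912 with an estimated correlation). The 2 were KLHL24 (log2 -0.95, adjusted p = 0.0324) and CCNG2, an atypical cyclin (-0.96, adjusted p = 0.0431). Immediate early genes were higher in 5 of 35, 10 when adjusted over the list alone with 1 lower (median 0.23, camera adjusted p = 4.11e-08, adjusted p = 0.218 with an estimated correlation). They included GADD45B (1.12, adjusted p = 0.0105), DUSP8 (0.91, adjusted p = 0.0153) and the antiproliferative gene BTG2 (0.80, adjusted p = 0.0318). Of 10 metallothionein list genes 1 was lower, MT1F (median -0.45, camera adjusted p = 4.93e-06, adjusted p = 0.263 with an estimated correlation). Of 27 sterol synthesis genes 1 was lower, HSD17B7 (log2 -0.81, adjusted p = 0.0431; list median -0.15, camera adjusted p = 0.000225, adjusted p = 0.263 with an estimated correlation). Of 24 p53 targets 2 were higher, BTG2 and PLK2 (0.69, adjusted p = 0.0397), with a list median of 0.10 (camera adjusted p = 0.0242, adjusted p = 0.36 with an estimated correlation).

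In 4 more lists past camera's threshold no gene passed limma's test over all genes. Medians were 0.23 for ribosome biogenesis (camera adjusted p = 4.93e-06, adjusted p = 0.306 with an estimated correlation), -0.12 for mTOR pathway components (0.00233 and 0.306), -0.09 for ribosomal proteins (0.0242 and 0.732) and 0.10 for actin cytoskeleton genes (0.0287 and 0.306). Within the larger and the smaller array set the sign differed for mTOR pathway components (-0.19 and 0.04) and ribosomal proteins (-0.16 and 0.04). In the same order the medians were 0.13 and 0.44 for immediate early genes, -0.21 and -0.02 for sterol synthesis, -0.39 and -0.22 for the amino acid response and -0.44 and -0.20 for the unfolded protein response. They were 0.16 and 0.35 for ribosome biogenesis, 0.07 and 0.25 for p53 targets and 0.06 and 0.16 for actin cytoskeleton genes. With the preset correlation, the ribosomal protein call also ended without Shigella 3, rapamycin 1 or rapamycin 2 and with quantile normalization (adjusted p from 0.156 to 0.852), and that of p53 targets without Shigella 3 (0.186) and in the larger array set (0.13). The actin call ended without Shigella 1, Shigella 3 or rapamycin 3, with the brighter probesets, above the 33rd percentile of signal and in the larger array set (0.0508 to 0.143). At an unadjusted p under 0.05, 6 of 27 ribosome biogenesis genes were higher, 4 of 24 actin genes were higher and 1 lower, 1 of 27 mTOR pathway components was higher and 4 lower (2 lower when adjusted over the list alone) and 0 of 48 ribosomal protein genes were on either side. The other 8 lists did not pass (camera adjusted p from 0.102 to 0.651). Their medians were 0.13 for the interferon response, 0.11 for heat shock, 0.03 for glycolysis and HIF1 targets, -0.05 for lysosome and autophagy, 0.05 for G1/S, -0.05 for G2/M, -0.07 for NRF2 targets and -0.01 for innate sensors. Median and mean differed in sign for glycolysis (mean -0.03) and innate sensors (0.04), and camera's direction was that of the mean.

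The count of 99 was 25 without Shigella 1, 37 without Shigella 2, 49 without Shigella 3, 38 without rapamycin 1 and 27 without rapamycin 2. With the array set as a block it was 320, including all 99. The 2 controls enter only the estimate of spread here, so without either of them the log2 differences stayed the same. HSD17B7, PLK2 and SESN2 lost their calls without any one of the 8 arrays (adjusted p from 0.0508 to 0.214). KLHL24, BTG2 and PJVK passed without rapamycin 3 and CCNG2 without Shigella 1, and each lost its call without any other array (adjusted p up to 0.176). CHAC1 lost its call without any one Shigella array or rapamycin 1 (adjusted p up to 0.128), and with only the brighter probesets of each gene it lay at log2 -0.60 (adjusted p = 0.35) and CCL20 at 0.89 (adjusted p = 0.243), while CXCL8 at 1.98 and CXCL10 at 1.82 passed (adjusted p = 0.00514 and 0.0163). With those probesets DDIT3, PJVK, MT1F, SLC1A4, VLDLR, DUSP8, HSD17B7, KLHL24, CCNG2 and PLK2 did not pass either (adjusted p from 0.0773 to 0.489). With the median over probesets CXCL8 lay at 1.81 (adjusted p = 0.000345), and BTG2, CHAC1, DNAJB9, DUSP8, GADD45B, HSD17B7, KLHL24, MT1F, PJVK, PLK2, SESN2 and VLDLR did not pass (adjusted p from 0.0607 to 0.381). SLC1A4, VLDLR, DNAJB9 and CCL20 lost theirs without Shigella 1, Shigella 2, rapamycin 1 or rapamycin 2 (adjusted p from 0.0536 to 0.132), and MT1F without Shigella 1, Shigella 3 or any one rapamycin array (adjusted p up to 0.181). HERPUD1 lost it without Shigella 1, Shigella 2 or rapamycin 2, DUSP8 without Shigella 1, Shigella 3 or rapamycin 2, GADD45B and ID3 without Shigella 1 or 2, HOXA5 and PLPP5 without Shigella 1 and DDIT4 without Shigella 2 (adjusted p from 0.0507 to 0.0913).

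Because both comparisons with untreated cells used the same 2 controls, their log2 changes correlate by construction. Across genes, which are not independent replicates, Pearson's r was 0.383, and in 100 simulated data sets with no effect it averaged 0.599 (0.583 to 0.620). The simulated arrays were independent, whereas deviations of control 2, Shigella 3 and rapamycin 3 correlated in the data (r of 0.609, 0.394 and 0.440 over their pairs), which the simulated values leave out; with the array set as a block the observed r was 0.290. The covariance was 0.0180 against a simulated mean of 0.0226 (0.0214 to 0.0244). With control 2 alone r was 0.684 against a simulated mean of 0.749, and the covariance was 0.0630 against 0.0451. With control 1 alone r was 0.438 against 0.749, and the covariance was 0.0225 against 0.0451, so the side of the simulated covariance depended on the control array. By limma's test 0 genes changed in both comparisons, against a mean of 0.03 (0 to 2) in the simulated data and 0.0037 for independent lists. At an unadjusted p under 0.05 in both, 39 genes were higher in both (simulated 104 to 161), 89 lower in both (simulated 104 to 154) and 9 opposite (simulated 0 to 4). The signs were the same for 63.4% of genes against 70.5% in the simulated data. Of the 22 genes that rose with infection, 11, ATF3 among them, lay above 0 with rapamycin, against 42.8% of all genes. The shared controls favour the same sign, so these 11 give no support for a shared response. Splitting the 2 controls would leave 1 in each part, so part of any shared signal may come from the controls.

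Markers of other cell types gave no gene past limma's threshold in any comparison. For Shigella minus control the medians were 0.02 for 14 leukocyte markers, 0.17 for 3 erythroid, -0.0082 for 9 fibroblast and -0.01 for 15 epithelial carcinoma markers, and -0.12 for 13 genes expressed in HEK293 cells; 1, 1, 0, 0 and 2 of them had an unadjusted p under 0.05. For rapamycin minus control they were -0.03, 0.01, 0.00086, 0.02 and -0.11 in that order, with 0, 0, 0, 0 and 1 at an unadjusted p under 0.05. For Shigella minus rapamycin they were 0.03, 0.23, -0.0051, -0.03 and 0.05, with 1, 0, 0, 1 and 2.

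Single probesets departed from the rest of their gene in 27 cases with Shigella and 16 with rapamycin by diffSplice, which called more probesets than this in simulated data with no change. With infection, 2 of the 5 probesets named by rule belong to NFKBIA and lay 2.26 and 2.04 below the rest of the gene in log2 change, while 1 probeset each of BAX (2.07), TARBP1 (2.11) and RCAN1 (1.93) lay above (adjusted p from 3.24e-08 to 5.71e-05). With rapamycin, probesets of SLTM (-3.12), PKD1 (-1.93), CDK4 (-2.47) and KALRN (-1.53) lay below and 1 of SUCO (2.03) above (adjusted p from 1.78e-07 to 0.00722). Tested with its own spread, 1 probeset passed for Shigella, in CXCL8 (log2 difference -3.56, adjusted p = 0.00521), and 0 for rapamycin. By that test 4233 and 5187 of 210792 had an unadjusted p under 0.05, below the share of 0.05 that would pass with no change. The CXCL8 probeset lay at 7.17 in the controls and 6.95 with Shigella, against a control median of 5.17 for the gene's other probesets, and the NFKBIA probesets lay at 7.67 and 7.88 and at 8.49 and 8.90, against 9.21. Levels of different probesets also depend on their probes, so these levels do not bear on the calls.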

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

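The tests on the shared day of the arrays and on the amino acid response list, the fits that use the array sets and the tests on the probeset calls were chosen only after the results they bear on had been seen. Among the probesets with no gene symbol given, which entered no gene value, 1 of 184297 passed limma's threshold with infection. Probeset 3321640 was 3.34 log2 units above the controls (7.11 against 3.77, adjusted p = 0.0331), higher in 3 of 3 Shigella arrays. With rapamycin 1 passed too, probeset 3430113, at 2.57 log2 units above the controls (6.40 against 3.83, adjusted p = 0.0473). Both control means, and the rapamycin mean of the second probeset, lay under the lower quartile of probeset values on every array (6.72 to 6.90) and were not tested against background, so the differences are those of the deposited signals. At an unadjusted p under 0.05 there were 5708 and 7053 of these 184297 probesets, below the share of 0.05 that would pass with no change.

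Control 2, Shigella 3 and rapamycin 3 deviated together from their group means, with a mean correlation of deviations of 0.481 over their 3 pairs. Different signal distributions of the arrays would lower this value after quantile normalization, but it was 0.494. Dim genes near background would leave less of it among bright genes, but among genes in the top tertile of mean signal it was 0.719. A day or batch shared by these 3 arrays stays open: the lowest of the 3 correlations was 0.256 over probesets with no gene symbol, and no label gives a day, a culture or a scan. The split crosses all 3 groups, so no treatment in the design accounts for it and no biological explanation was tested.

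Amino acid response genes lay above the controls with rapamycin, and 2 controls that happen to lie low could account for this. In Shigella minus rapamycin, whose difference holds no control, their median was -0.38 (camera p = 0.00987 with an estimated correlation before adjustment over the lists, 0.0912 after). This argues against low controls as the whole cause only if infection did not lower these genes, and the adjusted value did not pass. The array set as a block removed a median of -0.0022 (SD 0.033 over the 37 members) and left a median of 0.44 (SD 0.54) from 0.46 (SD 0.55). Controls and rapamycin arrays fall in both sets in similar shares, so the block could remove little of any set difference. The small part removed therefore does not decide whether the set is the cause. These SDs describe members that are correlated and are not errors of the medians. The call with an estimated correlation ended under that block (adjusted p = 0.0387 before and 0.237 after), where the correlation estimated between members went from 0.157 to 0.297. Within the larger set the median was 0.46 and within the smaller 0.41, and neither value holds a difference between sets. Both argue against the set as the whole cause, though each rests on a single control array. An effect of rapamycin or of its solvent stays open as a hypothesis. Medium and washes were similar in the infected cells. Under the same condition, the -0.38 above argues against those as the whole cause too.

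Unequal spread between probesets may account for some of the probeset calls. With no change in any probeset, diffSplice called 173 or more in simulated data for each comparison, against 27 and 16 in the real data. The simulated counts exceed the real ones, so they give no rate of false calls and no share due to unequal spread. Of the 27 calls with infection, 9 lay in the 23 genes that changed, out of 17843 genes. For those 9, unequal spread was not shown to be the cause. Of the 16 calls with rapamycin, 0 lay in a changed gene. Only 1 probeset, in CXCL8, passed when tested with its own spread too (log2 difference -3.56, adjusted p = 0.00521). That probeset lay at 7.17 in the controls and 6.95 with Shigella, while the gene as a whole rose (log2 2.83). The gene's other probesets had a control median of 5.17, but levels of different probesets also depend on their probes. PKD1's probeset had an SD of 2.77 between the 2 controls. A probeset that does not respond to the gene's RNA and a change in isoform use both stay open, and neither was tested.

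The 6 treated arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 99 changed genes and 12 lists past camera's threshold, and 1 of the 10 splits, the real one, gave as many of either; the highest of the other splits gave 0 genes and 6 lists. Each of those others sets 2 arrays of one treatment with 1 of the other, so part of the treatment difference is still in them. That mixing also widens the spread within each group for genes that differ between treatments. Few calls in those splits were therefore likely from the start, and 99 against 0 genes gives no separate support.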

How the results depend on the processing

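The fits with the array set as a block, those on the larger array set and the probeset test with its own spread were chosen only after the results were seen. Across 18 settings other than the reported one, 5310 values for 299 pairs of a named gene and a comparison held 4964 with the same direction and side of the threshold, 222 that no longer passed, 90 that newly passed and 34 of the other sign, none of a gene that had passed. Most of these pairs had not passed as reported and had no call to lose, so the 4964 overstates how firm the calls were. For Shigella minus control, rapamycin minus control and Shigella minus rapamycin, the reported 23, 3 and 99 changed genes became 11, 4 and 57 with the median over probesets, 16, 0 and 52 with the brighter probesets of each gene, 26, 6 and 95 with quantile normalization, 13, 7 and 50 among genes at or above the 33rd percentile of signal, and 15, 0 and 71 with only the 2 groups compared. They were 35, 39 and 72 with an unadjusted p under 0.05 and a 2-fold change, 32, 38 and 549 with array weights, 47, 18 and 320 with the array set as a block and 14, 68 and 214 in the larger array set alone. Over the fits without 1 array the counts ran from 7 to 19, from 0 to 14 and from 25 to 113; a control left alone in its group was assumed to vary like the other groups. The brighter probesets, the 2 groups alone and the loss of Shigella 1 each ended all 3 rapamycin calls. With the 2 groups alone or without Shigella 1, the log2 changes stayed at 2.45 for DDIT3, 1.74 for CTH and 1.66 for CHAC1. In those 2 fits only the estimate of spread differed. Without control 1 and without control 2 the changes were 2.32 and 2.57 for DDIT3, 1.62 and 1.87 for CTH and 1.71 and 1.60 for CHAC1. For the brighter probesets the cause was not tested. Lists past the threshold numbered 4 instead of 7 for Shigella minus control with quantile normalization, and 1, 1 and 1 instead of 7, 7 and 12 with an estimated correlation; without 1 array they ran from 6 to 8, 5 to 8 and 9 to 13. The correlation of both responses ran from 0.275 to 0.684, the latter without control 1, and the 0 genes changed in both became 2 in the larger array set, 1 with the array set as a block and 1 without rapamycin 3. Probesets called by diffSplice, 27 and 16, were 8 and 1 above the 33rd percentile of signal, 47 and 65 with the array set as a block and 1 and 0 with each probeset's own spread; without 1 array they ran from 9 (without Shigella 1) to 148 (without Shigella 3) and from 6 (without rapamycin 1) to 190 (without rapamycin 3). For Shigella they also moved to 15 without control 1 and 17 without control 2, and for rapamycin to 29 without Shigella 2 and 33 without Shigella 3. The cause of these changes was not tested, and signal over background, which would set the limit for dim genes, was not used here.

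Values of the other sign, none past the threshold as reported, were as follows, and the cause was not tested. For Shigella minus control, the median over probesets gave HSPD1 0.048 and TRIB3 0.027, the brighter probesets gave AKR1C1 0.051, MT1H -0.0088 and MYC 0.027, a common array median gave TRIB3 0.013 and the larger array set gave MT1B -0.021. For rapamycin minus control, the brighter probesets gave IFI44 -0.038, IL18 -0.057 and FOS -0.024. For Shigella minus rapamycin, the median over probesets gave ATF3 -0.094, the brighter probesets gave HSPA1L 0.40, and the larger array set gave ATF3 -0.0021 and EGR1 -0.21. Without 1 array, Shigella minus control ran from -0.90 to 0.085 for AKR1C1, -0.54 to 0.082 for MT1F, -0.039 to 0.51 for ASNS, -0.091 to 0.020 for TRIB3, -0.32 to 0.060 for HMOX1 and -0.23 to 0.060 for MYC. Rapamycin minus control ran from -0.20 to 0.18 for CXCL8 and -0.27 to 0.0028 for MTOR, and Shigella minus rapamycin from -0.095 to 0.26 for ATF3, -0.11 to 0.14 for EGR1 and -0.20 to 0.091 for MTOR.

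The replicate numbers were not taken to pair the arrays, since the labels speak of an experiment per sample and same-numbered controls and Shigella arrays deviated with r = 0.0767 and -0.632. For controls and rapamycin arrays r was 0.450 and -0.128, and for Shigella and rapamycin 0.152, 0.129 and 0.440. Shigella 2 correlated better with rapamycin 1 (0.430) than with its own number. The 2 controls deviate from their mean by exact opposites, so the values for control 1 and control 2 are not separate evidence. Which control was lost was not established, so control 2 may belong with Shigella 3 and rapamycin 3. In that case the r of -0.632 and -0.128 would not bear on pairing. A replicate block with control 2 moved in this way was not fitted. The replicate number as a block may thus pair the wrong arrays. With the replicate number as a block the 3 gene counts were 67, 121 and 190, the probeset counts 80 and 139 and the correlation of both responses 0.613, with 18 genes changed in both, and the interferon and mTOR component lists for Shigella minus control and the FOXO list for rapamycin minus control did not pass (adjusted p = 0.234, 0.143 and 0.138). That block also gave TRIB3 0.0030, HMOX1 0.0039 and MYC 0.099 for Shigella minus control.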

Other observations

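The choice of genes in both paragraphs was made only after their values were seen. Within the unfolded protein response list, log2 changes with rapamycin ran from -0.04 ± 0.21 (SE) for ATF6 to 1.22 ± 0.17 for HERPUD1. The chaperones HSPA5 and HSP90B1 lay at 0.28 ± 0.16 and 0.16 ± 0.15 (adjusted p = 0.953 and 0.971). None of these passed limma's test against the controls, and differences between members were not tested. Outside this list, the kinase EIF2AK3, which senses stress in the endoplasmic reticulum, lay at 0.49 ± 0.17 (adjusted p = 0.734). SEC24D, a coat component of vesicles leaving the endoplasmic reticulum, was lower with Shigella than with rapamycin (log2 -1.13 ± 0.16, adjusted p = 0.0134).

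CCND1, GRWD1, PDCD4 and SQSTM1, taken from different fixed lists, did not pass limma's test in any of the 3 comparisons. CCND1, cyclin D1, lay at log2 -0.50 ± 0.12 with rapamycin (adjusted p = 0.456), GRWD1, a ribosome assembly factor, at -0.46 ± 0.14 (adjusted p = 0.615), and PDCD4, an inhibitor of translation initiation, at 0.57 ± 0.16 (adjusted p = 0.576). SQSTM1, an autophagy adaptor of ubiquitinated cargo, lay at 0.36 ± 0.16 with Shigella (adjusted p = 0.998) and at -0.20 ± 0.16 with rapamycin (adjusted p = 0.968), a difference of 0.56 ± 0.14 (adjusted p = 0.159).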
